A study of Mus musculus with 19 samples.

How the data were processed

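RNA was extracted from whole kidneys of mice of strain B6C3F1/J with the RNeasy mini kit, and polyadenylated RNA was made into libraries with the Illumina TruSeq kit, per the labels' protocols. The submitters' processing notes name Trim Galore 0.5.0, Bismark 0.19.1, STAR 2.2.1 and RSEM 1.3.1 and the genome build mm10, without saying which tool made which file. The deposited values of the 5 RNA libraries are TPM per gene, transcript abundances that sum to the same total in each library. The aligner settings, the annotation release and the strand setting are not given in the sources used here. TPM keep no read number, so depth is unknown, no interval for counting error can be given, and an exact 0 may be a failed estimate. Poly(A) selection measures histone and other poorly adenylated RNAs unreliably, and reads from near-identical gene copies are divided by estimate.

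Each file lists 54146 Ensembl gene identifiers, of which 52480 (96.9%) were paired with a symbol by a table of gene names. Chromosomes, positions and gene types come from RefSeq for assembly GRCm38.p6, the same build family as mm10, matched by symbol, and 12453 tested genes had a position. The group of each library was taken from its title and genotype label: 3 controls and 2 KspCre DKO. The bisulfite libraries (2 whole-genome and 12 reduced-representation) are not analysed here. No technical batch is given in the labels.

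The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), empirical Bayes with an intensity trend, two-sided, for the 13963 genes with a mean of at least 1 TPM over the 5 libraries. P-values were adjusted by Benjamini-Hochberg, and adjusted p below 0.05 was called. Log2 fold changes are on the log2(TPM + 1) scale, KspCre DKO minus control, and understate the change of low genes. For a single gene an exact permutation of 3 against 2 libraries makes 10 splits and cannot give a p below 0.1. Groups of 3 and 2 libraries without overlap arise by chance in 20% of genes, both directions together.

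The 34 gene lists were fixed before the data were examined and were tested with limma camera, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists with at least 5 tested members. Camera compares a list with all other tested genes, so a list can be called higher while its median lies near 0. Camera with an estimated correlation and fry were the alternatives. In simulated libraries with lists of 25 genes shifted by 0.9, 100% were called with the preset correlation and 5% with an estimated one. Genes were drawn independently there, so the simulation does not show which test is right for lists of correlated genes. Genes shared between lists count in each. Counts adjusted over the list alone use Benjamini-Hochberg within that list. Chromosomes were compared by Fisher's exact test on genes with unadjusted p below 0.01, and again, chosen after seeing the data, without genes of chromosome 3 that start within 100000 bases of an Hsd3b gene.

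The rule for named genes was fixed before the data were examined. It takes the methyltransferase genes first, then in each direction up to 10 called genes of largest fold change whose groups do not overlap and whose symbol is not a predicted model, pseudogene or mitochondrial gene. Where fewer than 5 passed, the gene of smallest p with an absolute log2 fold change of at least 0.58 filled the place. In each called list it takes the 4 members of smallest p, in other lists up to 2, and a set of anchor markers. A gene that this rule names is not reported here. ENSMUSG00000045104.8, the Rps3a, Tpm3 and Rplp0 copies, Hsd3b2 and the genes in the closing observations not covered by this rule were chosen after their values were seen.

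The alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, TPM rescaled without mitochondrially encoded genes, empirical Bayes without trend or robust, array weights, the replicate number as a block, and each library left out in turn. Rescaling without the 25 most abundant genes and testing RefSeq protein-coding genes alone were chosen after seeing the data. The gene test was tested on 20 sets of simulated libraries with 200 changed genes each, drawn from genes above about 5 TPM in the controls. In these sets 5.41% of all calls were false. Simulated genes were independent and equally variable in each library. The deposited libraries differ in complexity, so that share does not measure the false calls among them. The variances of the simulated genes were drawn from the prior fitted to these libraries, after a first draw from moderated variances gave more false calls.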

Results

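Messenger RNA was measured by RNA sequencing in whole mouse kidneys at 3 weeks of age, postnatal day 21. Dnmt3a and Dnmt3b encode the enzymes that place new methyl groups on DNA, and the study asked how their loss during kidney development affects the organ and its fetal enhancers. The control group held 3 libraries from animals that carry floxed Dnmt3a and Dnmt3b genes without Cre. The KspCre DKO group held 2 libraries from animals with the same floxed genes and a Cre driven by the Ksp-cadherin promoter, which is active in kidney tubule epithelium. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these libraries. The other 14 of the 19 samples of the series, which were bisulfite libraries, are not analysed here. The values are TPM, transcript abundances scaled to a fixed sum per library, which keep no sequencing depth, so the depth of each library is unknown.

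The libraries were not alike in complexity. KspCre DKO replicate 2 had 14710 genes above 0 TPM, against 20510 in KspCre DKO replicate 1 and 20075, 18703 and 18488 in control replicates 1, 2 and 3. Mitochondrially encoded genes held 31.0% of all TPM in KspCre DKO replicate 2, against 22.1% in KspCre DKO replicate 1 and 18.2%, 23.2% and 20.5% in the controls. Across tested genes, which are not independent replicates, log2 values of KspCre DKO replicate 2 correlated with those of the other libraries at r of 0.886 to 0.918. The other pairs of libraries reached 0.922 to 0.958.

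The targeted genes gave no check of the labels. Dnmt3a (chromosome 12, 3801559 to 3914443) stood at 13.2, 18.97 and 15.5 TPM in the controls and 9.98 and 14.2 TPM in the libraries labelled KspCre DKO, a log2 fold change of −0.37 ± 0.31 (SE; limma adjusted p = 0.709). Dnmt3b (chromosome 2, 153649411 to 153687730) stood at 1.82, 2.86 and 1.98 TPM against 2.29 and 3.25 TPM, a log2 fold change of 0.23 ± 0.38 (SE; adjusted p = 0.866). Dnmt1, the maintenance methyltransferase, stood at 8.39 ± 0.37 TPM (SD, n = 3) and 7.95 ± 0.15 TPM (SD, n = 2). Dnmt3l, a regulatory partner without catalytic activity, was at or below 0.44 TPM in each library. A floxed-exon deletion restricted to part of the cells of the organ need not lower the TPM of the whole gene, so every direction given here rests on the labels.

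Among 13963 tested genes, 14 were higher and 9 were lower in the libraries labelled KspCre DKO (limma, adjusted p below 0.05). Of the genes named by rule, the smallest p was that of Fcgbp (ENSMUSG00000047730.17, chromosome 7, 28071236 to 28120864), which encodes a mucin-like IgG Fc binding protein. It rose from 3.11 ± 1.65 TPM (SD, n = 3) to 56.6 ± 4.04 TPM (SD, n = 2), a log2 fold change of 3.88 ± 0.37 (SE; adjusted p = 0.00999). Muc20, a membrane mucin, rose from 11.8 ± 7.38 to 143 ± 74.5 TPM (adjusted p = 0.0485). Rnf183 (chromosome 4, 62427540 to 62435250), a ubiquitin ligase of the collecting duct, rose from 17.8 ± 3.34 to 88.4 ± 14.6 TPM (log2 fold change 2.25 ± 0.29 SE, adjusted p = 0.0451). Epor, the erythropoietin receptor (chromosome 9, 21958897 to 21963576), rose from 5.96 ± 1.08 to 30.6 ± 2.84 TPM (log2 fold change 2.19 ± 0.30 SE, adjusted p = 0.0462). The gasdermin genes Gsdmc2 and Gsdmc3, neighbours on chromosome 15, rose from 13.2 ± 1.25 to 60.3 ± 2.20 TPM and from 8.59 ± 0.86 to 48.0 ± 14.3 TPM. These are close paralogs, so the split of reads between them is uncertain. Calml3 rose by a log2 fold change of 2.77, Crispld2 by 2.38 and Pdia2 by 2.98. Hist2h2bb was listed at 0 in each control and at 8.73 and 38.7 TPM in the libraries labelled KspCre DKO.

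Of the genes that fell, Ckb, brain-type creatine kinase (chromosome 12, 111669355 to 111672338), went from 235 ± 22.0 to 65.2 ± 8.63 TPM (log2 fold change −1.83 ± 0.25 SE, adjusted p = 0.0462). Atp5e, a subunit of the mitochondrial ATP synthase, went from 1832 ± 228 to 569 ± 70.1 TPM (log2 fold change −1.68 ± 0.23 SE, adjusted p = 0.0462). Hsd3b4, a 3-ketosteroid reductase gene (chromosome 3, 98499071 to 98510579), stood at 270, 407 and 408 TPM in the controls, and at 0 and 10.1 TPM in the libraries labelled KspCre DKO (adjusted p = 0.0379). Ugt1a9 was at 7.07, 10.3 and 10.5 TPM in the controls and listed at 0 in both libraries labelled KspCre DKO (adjusted p = 0.0224). Ugt1a9 shares exons with other Ugt1a genes and Hsd3b4 has close paralogs, so both values are uncertain. Hist2h2aa2, the gene of smallest p below these, did not pass: 104 ± 3.87 against 31.2 ± 0.28 TPM (adjusted p = 0.0512).

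**Figure D1:**
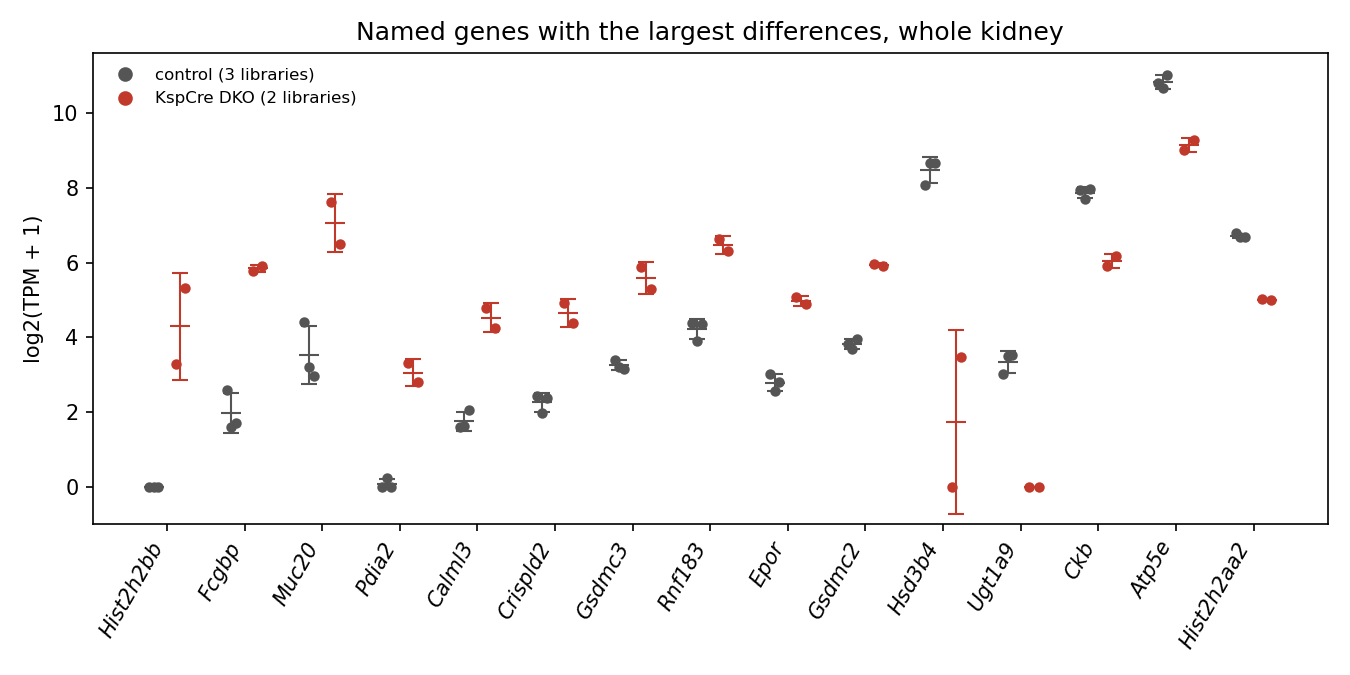
Expression in log2(TPM + 1) of the 10 higher and 4 lower genes named by rule and of Hist2h2aa2, which did not pass, in each library (points), with group means and SDs (bars). In each gene shown, the 2 libraries labelled KspCre DKO lie on one side of the 3 controls; Hist2h2bb is at 0 in the controls and Ugt1a9 at 0 in both libraries labelled KspCre DKO.

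The called groups did not overlap for any of the 23 genes, while 26.1% of all tested genes also had no overlap, where chance gives 20%. The count rests on single libraries: it was 45 higher and 14 lower without control replicate 1, 7 and 3 without control replicate 2, and 5 and 3 without control replicate 3. Without KspCre DKO replicate 1 it was 90 higher and 470 lower, and without KspCre DKO replicate 2 it was 3 and 3. With the remaining library of that group taken to vary like the controls, neither last value has a replicate of its own behind it. Of the 14 called genes named by rule, Fcgbp alone kept its call without control replicate 2 (adjusted p = 0.0365) or control replicate 3 (adjusted p = 0.0373), and Hsd3b4 alone without KspCre DKO replicate 2 (adjusted p = 0.00483). Without KspCre DKO replicate 1 Muc20 lost its call (adjusted p = 0.0545). Without control replicate 1 Pdia2, Crispld2, Gsdmc2, Ckb and Atp5e lost theirs (adjusted p = 0.0635, 0.0508, 0.0508, 0.0662 and 0.0508). The split between directions also moved with the scaling, to 24 higher and 7 lower with median-of-ratios scaling and 35 and 7 with quantile normalization. In simulated libraries of this size, 81.5% of genes changed by 3 log2 units were called, against 40.8% of those changed by 2 units and 0.882% of those changed by 1 unit. The changed genes were drawn only from those above about 5 TPM in the controls, so these shares do not cover lower genes.

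Of the 23 called genes, 5 are annotated pseudogenes, and 3 of those are among the 4 smallest p-values. The smallest of all belonged to ENSMUSG00000045104.8, which has no symbol in the gene name table used and fell from 277 ± 61.7 to 0.36 ± 0.51 TPM, a log2 fold change of −7.70 (adjusted p = 7.53e-05). Rps3a3, a processed copy of the ribosomal protein gene Rps3a1, rose from 1.46 ± 0.74 TPM (SD, n = 3) to 339 ± 1.94 TPM (SD, n = 2; adjusted p = 7.53e-05). Its copy Rps3a2 rose from 10.5 ± 4.18 to 244 ± 115 TPM (adjusted p = 0.00999), a call lost without KspCre DKO replicate 2 (adjusted p = 0.0837). The parent gene Rps3a1 stood at 712 ± 123 against 184 ± 96.0 TPM (adjusted p = 0.081). The sum of these 3 copies was 724 ± 125 TPM in the controls and 768 ± 213 TPM in the libraries labelled KspCre DKO, a difference smaller than the spread. The copies Gm8730 of Rplp0 and Tpm3-rs7 of Tpm3 rose from 2.82 ± 0.62 to 178 ± 11 TPM and from 0.43 ± 0.33 to 66.5 ± 13.8 TPM. Reads may be shared between such copies, which was not examined by sequence, so these genes are reported as uncertain. Of 348 tested pseudogenes 1.44% were called, against 0.107% of other genes of known type. Pseudogenes also differed more within groups. Log2 differences over 2 were seen in 20.4% of them against 3.19% of others between the KspCre DKO libraries. Between control 1 and the mean of controls 2 and 3 the shares were 6.32% and 0.512%.

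**Figure D2:**
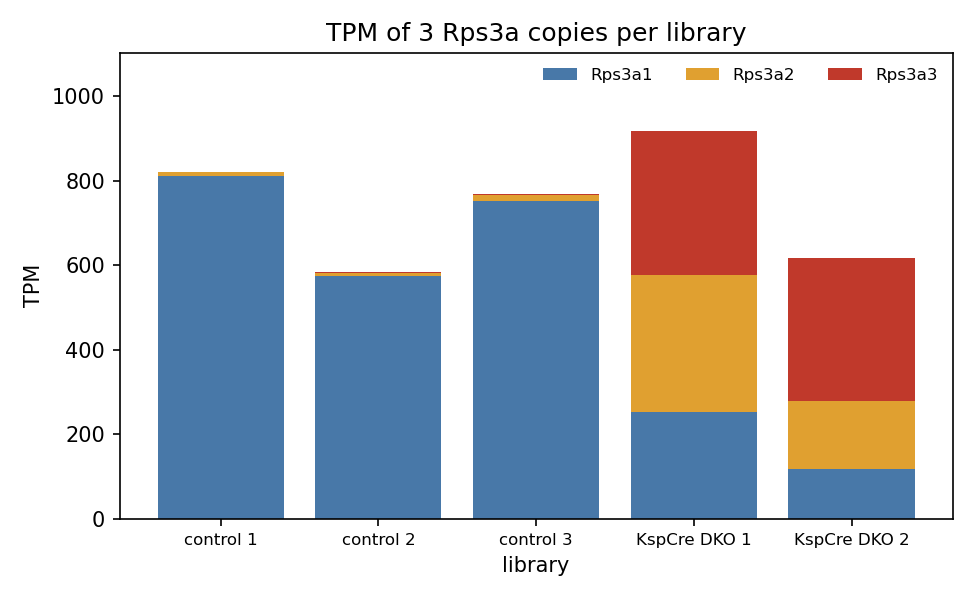
Stacked TPM of Rps3a1 and its copies Rps3a2 and Rps3a3 in each of the 5 libraries. The bar heights lie between 583 and 919 TPM in both groups, while Rps3a1 makes up most of each control bar and Rps3a2 and Rps3a3 most of each KspCre DKO bar.

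Markers of the thick ascending limb of the loop of Henle, the segment that reabsorbs salt through Slc12a1 and secretes uromodulin, fell as a list. Of 23 tested members 20 were lower and 3 higher, with a median log2 fold change of −0.91 against −0.14 for all tested genes (camera adjusted p = 8.94e-08, and adjusted p = 0.743 with an estimated correlation). No member passed on its own over all genes, and 11 passed when adjusted over the list alone, all lower. Slc12a1 (chromosome 2, 125152510 to 125230002), the sodium-potassium-chloride cotransporter, stood at 394, 562 and 519 TPM in the controls against 191 and 61.3 TPM (log2 fold change −2.15 ± 0.44 SE, adjusted p = 0.141). Umod (chromosome 7, 119462708 to 119479262), which encodes uromodulin, stood at 611 ± 168 against 239 ± 65.1 TPM (log2 fold change −1.34 ± 0.30 SE, adjusted p = 0.173). Wfdc15b, Tmem207 and the prostaglandin receptor gene Ptger3 differed by log2 fold changes of −1.35, −1.46 and −2.59 (adjusted p = 0.142, 0.162 and 0.171). The list was called lower in each refit that left out a control library. Its median was −1.28 without KspCre DKO replicate 1 and −0.82 without KspCre DKO replicate 2, against −0.39 and 0.13 for all genes. Each of these refits holds 1 KspCre DKO library. The test with an estimated correlation found 5% of lists shifted by 0.9 in simulated data, where the main test found 100%. Simulated genes were independent, whereas the correlation estimated for this list was 0.49. The simulation therefore cannot show which of the tests is right for it.

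Markers of the distal convoluted and connecting tubules, which fine-tune salt and calcium, were lower as a list, with 15 of 19 members lower and a median of −0.44 (camera adjusted p = 0.0361, and adjusted p = 0.673 with an estimated correlation). Adjusted over the list alone, 1 member was higher and 2 were lower; none passed over all genes. The calcium-binding protein gene S100g stood at 3661 ± 334 against 1940 ± 433 TPM and Slc16a7 at 22.1 ± 3.12 against 9.87 ± 1.56 TPM (adjusted p = 0.201 and 0.247), and Tmem52b at 57.6 ± 5.68 against 33.8 ± 14.6 TPM. Members did not move one way: Slc12a3, the thiazide-sensitive cotransporter, stood at 138 ± 14.6 against 206 ± 35.4 TPM and Phactr1 at 20.9 ± 12.6 against 75.3 ± 2.76 TPM. This list was not called without control replicate 1 (camera adjusted p = 0.0613) or control replicate 2 (camera adjusted p = 0.0801). Nor was it called without KspCre DKO replicate 1, which leaves 1 library in that group. It was called in 7 of 13 refits with another setting, among them the replicate block, whose fold changes do not draw on control replicate 3.

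Markers of collecting duct principal cells, which reabsorb water and sodium, rose as a list (camera adjusted p = 0.00222, and adjusted p = 0.673 with an estimated correlation). Of 23 members 14 were higher and 9 lower, with a median of 0.24; none passed over all genes, and adjusted over the list alone 8 were higher and 2 lower. Aqp2, the vasopressin-regulated water channel (chromosome 15, 99579056 to 99584545), stood at 347, 240 and 426 TPM in the controls against 1414 and 1218 TPM (log2 fold change 2.0 ± 0.29 SE, adjusted p = 0.0512). The transcription factor genes Elf5 and Gata3 stood at 10.8 ± 5.61 against 62.2 ± 12.1 TPM and at 16.1 ± 1.02 against 36.6 ± 2.73 TPM (adjusted p = 0.0705 and 0.188). Fxyd4, a regulator of the sodium pump, stood at 282 ± 56.4 against 648 ± 151 TPM (adjusted p = 0.178). Hoxd10, a member of the same list, went the other way, at 13.0, 18.0 and 23.2 TPM against 8.53 and 1.66 TPM. The list was not called without KspCre DKO replicate 2 (adjusted p = 0.193).

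**Figure D3:**
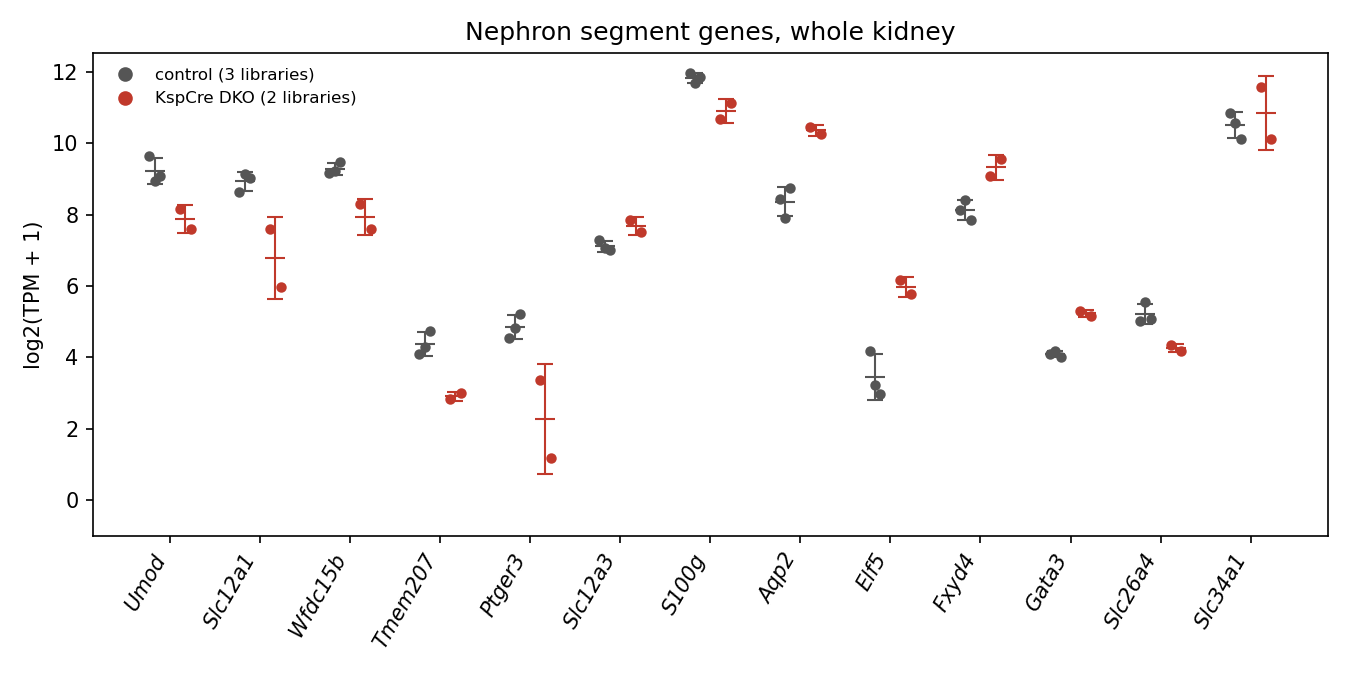
Expression in log2(TPM + 1) of nephron segment genes in each library (points), with group means and SDs (bars). Umod, Slc12a1, Wfdc15b, Tmem207 and Ptger3 lie lower in both libraries labelled KspCre DKO than in the 3 controls, and Aqp2, Elf5, Fxyd4 and Gata3 lie higher; no gene shown passed over all genes.

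Urothelial genes rose as a list, with 8 of 12 members higher and a median of 0.34 (camera adjusted p = 0.00263, and adjusted p = 0.673 with an estimated correlation). Gsdmc2 was the 1 member that passed over all genes, and adjusted over the list alone 3 were higher and 1 lower. Psca stood at 45.2 ± 22.7 against 248 ± 96.9 TPM (adjusted p = 0.081) and Upk3b, an uroplakin, at 3.68 ± 2.50 against 15.8 ± 4.10 TPM (adjusted p = 0.18), while Krt14, a basal keratin, stood at 3.28 ± 0.67 against 0.60 ± 0.16 TPM. The list was not called without KspCre DKO replicate 2 (adjusted p = 0.193). Genes near loci associated with human kidney function, 31 tested, were called higher (camera adjusted p = 0.0492, and adjusted p = 0.762 with an estimated correlation), with 17 higher and 14 lower and a median of 0.01. Adjusted over the list alone 4 were higher and 1, Umod, was lower. Tbx3, Mpped2 and Tfdp2 stood at 5.48 ± 2.0 against 28.4 ± 3.04 TPM, 4.87 ± 2.0 against 17.9 ± 4.40 TPM and 6.73 ± 2.01 against 18.2 ± 1.87 TPM (adjusted p = 0.0705, 0.162 and 0.201). That call was lost without control replicate 3 (camera adjusted p = 0.0761) and without KspCre DKO replicate 1, which leaves 1 library in that group. It held in only 4 of 13 refits with another setting, and not with the replicate block, whose fold changes do not draw on control replicate 3.

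Fibroblast, macrophage and adipose lists were lower. Of 34 fibroblast and matrix genes 28 were lower, with a median of −0.75 (camera adjusted p = 9.03e-04, and adjusted p = 0.762 with an estimated correlation); 1 passed adjusted over the list alone and none over all genes. Postn (periostin) stood at 18.2 ± 8.94 against 1.82 ± 1.90 TPM, Mmp2 at 11.8 ± 5.22 against 3.30 ± 0.96 TPM and Col6a1 at 29.7 ± 11.2 against 12.7 ± 0.66 TPM (adjusted p = 0.113, 0.229 and 0.362). Without KspCre DKO replicate 1 the direction of the test turned and this list was not called (adjusted p = 0.965), with a median of −0.63 against −0.39 for all genes in that refit. All 13 macrophage and myeloid markers were lower, with a median of −0.74 (camera adjusted p = 0.0025, and adjusted p = 0.673 with an estimated correlation), and none passed on its own over all genes or adjusted over the list alone. Lyz2 stood at 21.6 ± 7.88 against 5.80 ± 4.18 TPM and C1qc at 11.9 ± 4.30 against 4.53 ± 2.30 TPM. In KspCre DKO replicate 2, the library with the fewest genes above 0, S100a9 and Fcer1g were listed at 0, against 2.01 and 8.37 TPM in KspCre DKO replicate 1. This call was lost without KspCre DKO replicate 1 (adjusted p = 0.344), where the median was −1.13. The 5 tested adipose genes were also lower, with a median of −0.80 (camera adjusted p = 0.0194, and adjusted p = 0.673 with an estimated correlation), and Fabp4 at 241 ± 66.8 against 83.1 ± 10.2 TPM was the 1 that passed adjusted over the list alone. Lpl, Pparg and Cfd had log2 fold changes of −1.03, −0.80 and −0.75. The adipose call was lost without KspCre DKO replicate 1 (adjusted p = 0.213) or KspCre DKO replicate 2 (adjusted p = 0.0542).

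Genes tied to growth and embryonic patterning were lower as lists. Of 24 imprinted genes 18 were lower, with a median of −0.35 (camera adjusted p = 0.00555, and adjusted p = 0.762 with an estimated correlation), and 7 passed adjusted over the list alone, all lower, against none over all genes. Mest stood at 8.65 ± 2.66 against 2.33 ± 0.81 TPM, Dlk1 at 5.26 ± 1.33 against 1.17 ± 0.64 TPM and Peg3 at 14.5 ± 1.26 against 6.14 ± 2.09 TPM (adjusted p = 0.212, 0.215 and 0.26), and Meg3 at 11, 7 and 5.56 TPM against 2.81 and 0 TPM. Without KspCre DKO replicate 1 the list had adjusted p = 0.123. Of 27 cell cycle genes 25 were lower, with a median of −0.43 (camera adjusted p = 0.0167, and adjusted p = 0.762 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Hmgb2, Rrm2, Ccnb2 and Mcm6 had log2 fold changes of −1.44, −1.17, −1.56 and −1.21. That call was lost without control replicate 1 (adjusted p = 0.33) or KspCre DKO replicate 1 (adjusted p = 0.384). Posterior Hox genes, which pattern the lower trunk, were lower in 13 of 16, with a median of −0.48 (camera adjusted p = 0.0167, and adjusted p = 0.762 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Hoxd10, Hoxc6, Hoxc8 and Hoxa11 had log2 fold changes of −1.88, −1.10, −1.01 and −1.06. The Hox call was lost without control replicate 2 (adjusted p = 0.0683), control replicate 3 (adjusted p = 0.05004) or KspCre DKO replicate 1 (adjusted p = 0.309).

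Immediate early, tubule injury and interferon-stimulated lists were higher. Immediate early genes had 12 of 19 members higher, a median of 0.10 and 1 member passing adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.673 with an estimated correlation). Fosl2 stood at 4.5 ± 0.14 against 14.8 ± 0.32 TPM, Ccn1 at 10.2 ± 2.52 against 23.3 ± 4.0 TPM and Zfp36 at 20.2 ± 1.46 against 40.0 ± 15.5 TPM, while Ier3 stood at 29.6 ± 4.52 against 13.5 ± 7.08 TPM. Tubule injury genes had 17 of 28 members higher and a median of 0.26 (camera adjusted p = 0.024, and adjusted p = 0.762 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone. Lcn2 (neutrophil gelatinase-associated lipocalin) stood at 7.95 ± 4.09 against 23.3 ± 2.78 TPM (adjusted p = 0.264), Plaur at 6.44 ± 2.10 against 18.3 ± 1.53 TPM and Krt18 at 73.5 ± 14.7 against 164 ± 58.2 TPM. Members of that list also went down, Anxa3 at 44.9 ± 11.6 against 15.7 ± 2.59 TPM, and the injury marker Havcr1 was at or below 0.27 TPM in each library. Interferon-stimulated genes had 21 of 35 members higher and a median of 0.17 (camera adjusted p = 0.0194, and adjusted p = 0.762 with an estimated correlation), with none passing adjusted over the list alone. Ifit1, Ifit3 and Isg15 had log2 fold changes of 1.06, 0.68 and 0.61 and Bst2 of −0.75. The immediate early call was lost without KspCre DKO replicate 2 (adjusted p = 0.155). The injury call was lost without control replicate 2 (adjusted p = 0.0683) or KspCre DKO replicate 2 (adjusted p = 0.315). The interferon call was lost without control replicate 2 (adjusted p = 0.457), KspCre DKO replicate 1 (adjusted p = 0.102) or KspCre DKO replicate 2 (adjusted p = 0.0721).

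Clock, mitochondrial and erythroid lists were higher. Circadian clock genes had 13 of 17 members higher and a median of 0.28 (camera adjusted p = 0.0277, and adjusted p = 0.762 with an estimated correlation), none passing adjusted over the list alone. Dbp stood at 133, 23.3 and 56.7 TPM against 239 and 166 TPM, Nr1d1 at 26.8, 8.33 and 11.4 TPM against 55.4 and 32.5 TPM, Ciart had a log2 fold change of 1.13, and Nfil3 stood at 7.27 ± 1.99 against 2.73 ± 0.09 TPM. That call was lost without control replicate 3 (adjusted p = 0.0582) or KspCre DKO replicate 1 (adjusted p = 0.384). The 13 mitochondrially encoded genes had a median of 0.30 with 10 higher (camera adjusted p = 0.0167, and adjusted p = 0.762 with an estimated correlation), none passing adjusted over the list alone, and mt-Co1, mt-Cytb, mt-Nd2 and mt-Atp8 had log2 fold changes of 0.49, 0.40, 0.45 and 0.28. With quantile normalization mt-Nd2 and mt-Atp8 turned to −0.08 and −0.13. Without KspCre DKO replicate 2, the library with the highest mitochondrial share, the list was in the other direction (adjusted p = 0.144), and without control replicate 1 it was not called (adjusted p = 0.101). Erythroid genes had 7 of 9 members higher and a median of 1.04 (camera adjusted p = 0.0123, and adjusted p = 0.762 with an estimated correlation); 1 member passed adjusted over the list alone, and it was lower. That member was Tfrc, the transferrin receptor, at 26.3 ± 1.46 against 5.09 ± 6.53 TPM. Hba-a2 stood at 1336, 204 and 1181 TPM in the controls against 2941 and 3765 TPM, Hbb-bt at 303, 23.2 and 60.02 TPM against 369 and 367 TPM, and Bpgm at 15.7 ± 6.44 against 32.1 ± 5.89 TPM. The erythroid call was lost without KspCre DKO replicate 1 (adjusted p = 0.108) or KspCre DKO replicate 2 (adjusted p = 0.423).

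The remaining 13 of 30 tested lists were not called. Nephron progenitor markers, which a kidney of this age has largely lost, had 13 of 14 members lower (median −0.49, camera adjusted p = 0.0743), and the progenitor factor Six2 was at or below 0.09 TPM in each library. Cited1 stood at 5.49, 10.8 and 15.3 TPM against 4.09 and 0 TPM. Early nephron and fetal kidney genes were divided, with 8 higher and 13 lower (adjusted p = 0.979): Wnt4 stood at 2.98 ± 0.93 against 13.7 ± 0.03 TPM (adjusted p = 0.0918) and Dlk1 was lower. Ureteric bud tip markers had a median of −0.14 but a mean of 0.38 and a test direction of higher (adjusted p = 0.106), with Wnt9b at 3.17 ± 1.3 against 26.1 ± 9.71 TPM (adjusted p = 0.0512). Stromal progenitor markers had a median of −0.51 (adjusted p = 0.198). Proximal tubule markers had a median of −0.03, a mean of 0.14 and a test direction of higher (adjusted p = 0.505); the phosphate transporter gene Slc34a1 stood at 1492 ± 357 against 2078 ± 1378 TPM. Intercalated cell markers had a median of −0.50 (adjusted p = 0.0836), with Adgrf1 at 1.08 ± 0.71 against 13.3 ± 6.37 TPM and Slc26a4, encoding pendrin, at 36.6 ± 7.92 against 18.2 ± 1.64 TPM. Podocyte, endothelial and fatty acid oxidation lists had medians of −0.22, −0.14 and −0.34 (adjusted p = 0.106, 0.25 and 0.102). Among lymphocyte markers the B cell genes Cd79b and Igkc stood at 1 ± 0.52 against 6.53 ± 4.5 TPM and 6.61 ± 3.67 against 24.1 ± 18.4 TPM (adjusted p = 0.252 and 0.397). Lymphocyte markers and cholesterol synthesis genes had medians of 0.39 and 0.03 (adjusted p = 0.25 and 0.236), and the DNA methylation machinery and heat shock lists had medians of −0.12 and −0.14 (adjusted p = 0.867 and 0.941). No member of these 13 lists passed over all genes. Adjusted over the list alone, 4 ureteric bud tip genes and 1 intercalated cell gene were higher, 1 stromal progenitor and 1 endothelial gene were lower, heat shock genes had 3 higher and 3 lower, early nephron genes had 2 higher and 3 lower, and the other 7 lists had none.

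Some of these lists passed when 1 library was left out. Without control replicate 1, proximal tubule, lymphocyte and cholesterol synthesis lists were higher and the intercalated cell list lower (adjusted p = 0.0156, 0.0118, 0.0168 and 0.0276). Without control replicate 2, nephron progenitor, endothelial and podocyte lists were lower (adjusted p = 0.0157, 0.0157 and 9.24e-05). Without control replicate 3 the fatty acid oxidation list was lower (adjusted p = 0.0101), and without KspCre DKO replicate 2 proximal tubule markers were higher and intercalated cell markers lower (adjusted p = 0.0198 and 0.0361). For lists that did not pass, the direction of the test, which compares a list with all other genes, also turned: early nephron (adjusted p = 0.622), proximal tubule (adjusted p = 0.848) and heat shock (adjusted p = 0.448) without control replicate 3, and lymphocyte without control replicate 2 (adjusted p = 0.992) or KspCre DKO replicate 2 (adjusted p = 0.706). Without KspCre DKO replicate 1, early nephron (adjusted p = 0.647), proximal tubule (adjusted p = 0.384) and DNA methylation machinery (adjusted p = 0.723) turned in the test. Their medians in that refit were −0.50, −0.46 and −0.11, none of them above 0, against −0.39 for all genes.

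**Figure D4:**
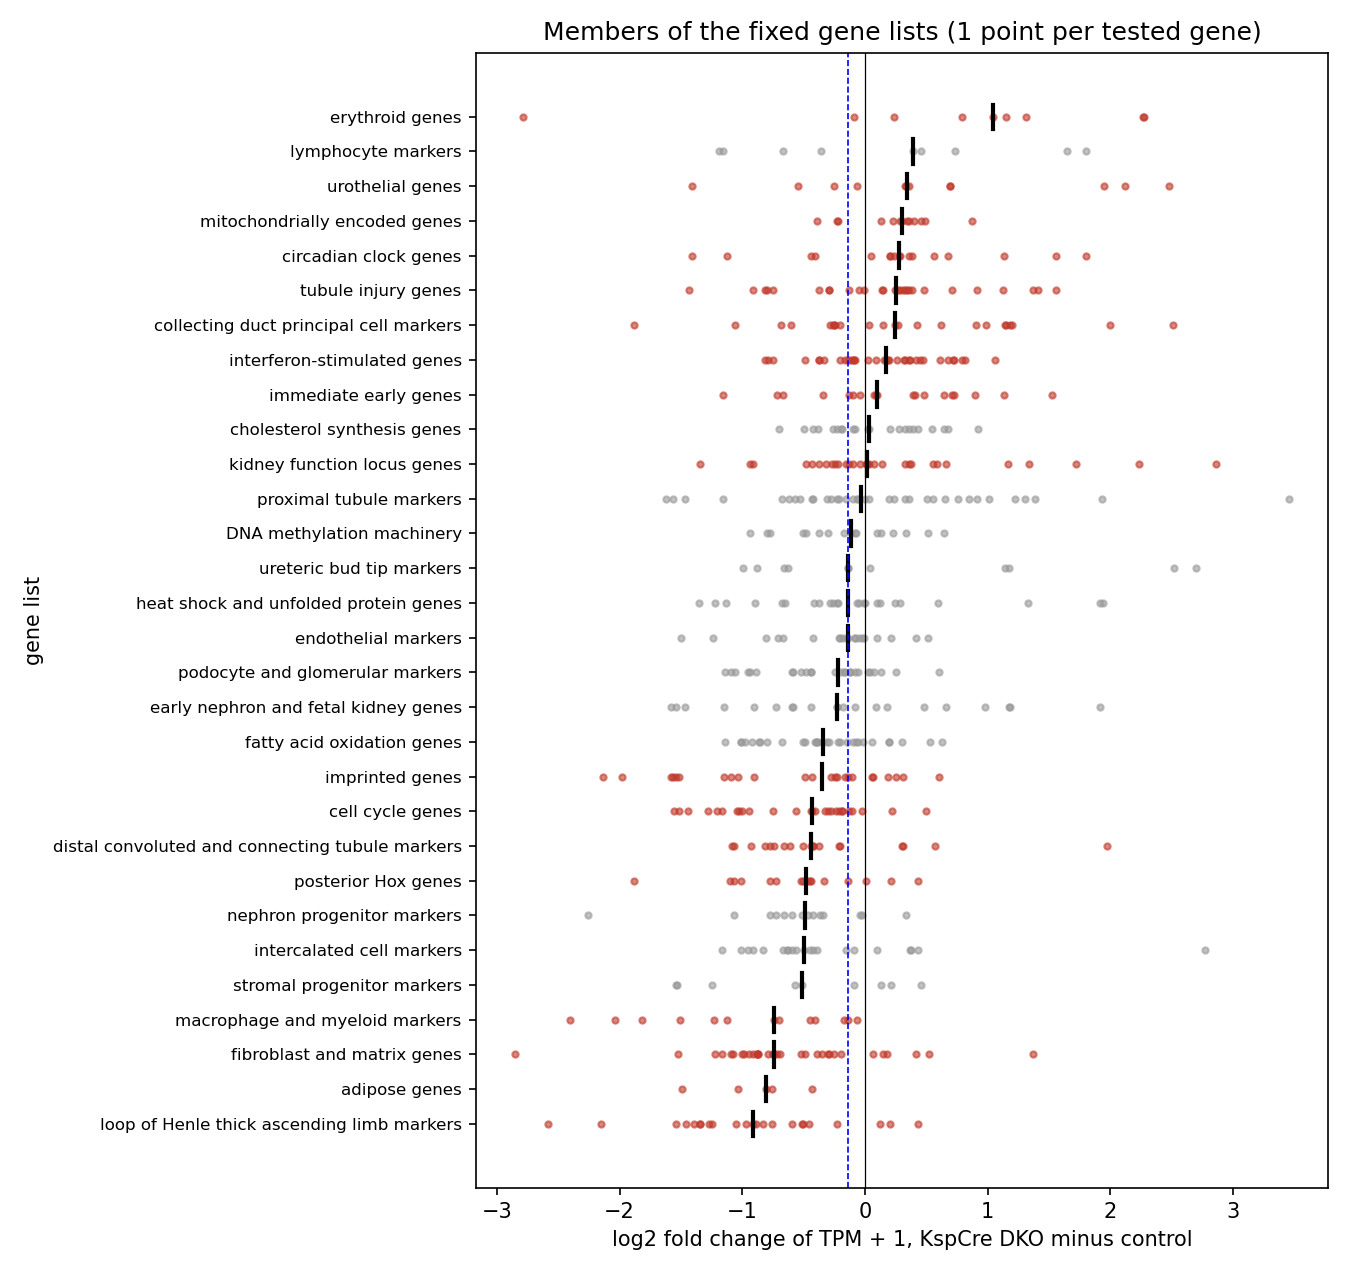
Log2 fold change of TPM + 1, KspCre DKO minus control, of each tested member (points) of the 30 tested gene lists, ordered by the list median (black tick), with the median of all tested genes, −0.14, as a dashed line. Red lists are the 17 called in the main test and grey lists the 13 that were not; the lowest median is that of the thick ascending limb list at −0.91, and the highest that of the erythroid list at 1.04.

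Another 4 lists had fewer than 5 members at a mean of at least 1 TPM and were not tested. Of 44 germline genes whose promoters are methylated in somatic cells, 42 had a row in the files, and 36 of those stayed below 1 TPM in each library of both groups. Adrenal, skeletal muscle and sex-linked genes had 3, 2 and 4 members at a mean of at least 1 TPM.

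Genes of small p were over-represented on 1 chromosome. On chromosome 3, 37 of 650 tested genes had an unadjusted p below 0.01, or 5.69%, against 3.14% of genes elsewhere (Fisher's exact test, adjusted p = 0.0194 over 21 chromosomes, two-sided). No chromosome was called at thresholds of 0.001 or 0.05. The call rests on the cluster of Hsd3b genes and their neighbours, where 6 of 9 genes were below 0.01: without these 9 genes chromosome 3 had 31 of 641 (adjusted p = 0.226). Hsd3b4 was the only gene with a position on chromosome 3 that was called over all genes. The parent genes Rps3a1 and Tpm3 of the copies described above, neither of them called, also lie there, at 86137940 to 86142668 and 90072651 to 90100902.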

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

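Rescaling without the 25 most abundant genes, testing protein-coding genes alone and leaving out the Hsd3b cluster were chosen after seeing the data. The 125 named genes tested kept their direction in 1583 of 1588 refits with another setting and in 622 of 624 refits without 1 library. Most were named for a small p or for groups without overlap. Leaving out a library cannot turn the direction of a gene whose groups do not overlap. The second count was therefore largely fixed by the choice of genes and is no measure of stability. The first count was partly fixed as well. Changing the filter, the empirical Bayes settings or the set of genes tested leaves the log2 fold change of a gene as it was, so its direction could not turn there. On the log2 scale Dnmt1 turned to 0.0338 with median-of-ratios scaling, 0.0325 without mitochondrially encoded genes and 0.11 without the 25 most abundant genes. With quantile normalization mt-Nd2 and mt-Atp8 turned to −0.0783 and −0.13. Without 1 library Slc34a1 ranged from −0.41 to 1.06 and Rplp0 from −0.87 to 0.0213. The 14 genes higher became 7 with a pseudocount of 0.1, 28 with a pseudocount of 5, 3 without a filter, 24 with median-of-ratios scaling, 35 with quantile normalization, 26 without mitochondrially encoded genes, 6 without trend, 3 with array weights, 37 without the 25 most abundant genes and 24 among protein-coding genes. The 9 genes lower became 1 without a filter, 3 without trend and 2 with array weights. Leaving out 1 library gave 3 to 90 genes higher and 3 to 470 lower, and 3 to 11 lists higher and 1 to 9 lower, against 9 and 8. Lists called higher were 5 without a filter and lists called lower 3 at a mean of at least 5 TPM. Both counts were 0 with an estimated correlation and 0 with fry, where 0 and 4 lists had an unadjusted p below 0.05. The 1 chromosome called became 0 at thresholds of 0.001 and 0.05 and 0 with genes of the Hsd3b cluster left out. The median log2 fold change of all genes, −0.14, moved by 0.12 with quantile normalization, 0.17 without the 25 most abundant genes, −0.26 without KspCre DKO replicate 1 and 0.27, to 0.13, without KspCre DKO replicate 2. The cause was not tested for these changes, beyond the fewer genes or libraries some settings leave.

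At a mean of at least 5 TPM calls were lost at adjusted p of 0.0933 (distal tubule), 0.0933 (interferon), 0.0523 (imprinted), 0.0933 (posterior Hox), 0.103 (cell cycle). With median-of-ratios scaling calls were lost at adjusted p of 0.0753 (distal tubule), 0.0804 (kidney function locus), 0.0804 (mitochondrial). With quantile normalization calls were lost at adjusted p of 0.0591 (distal tubule), 0.0591 (kidney function locus), 0.355 (mitochondrial). Without trend calls were lost at adjusted p of 0.0569 (distal tubule), 0.0626 (kidney function locus), 0.0567 (circadian clock), 0.0502 (mitochondrial). With array weights calls were lost at adjusted p of 0.0582 (distal tubule), 0.0582 (interferon), 0.0566 (erythroid). Without the 25 most abundant genes calls were lost at adjusted p of 0.0994 (distal tubule), 0.0643 (tubule injury), 0.0934 (kidney function locus). Without a filter calls were lost at adjusted p of 0.0629 (interferon), 0.159 (kidney function locus), 0.196 (mitochondrial), 0.0845 (erythroid). With the replicate block calls were lost at adjusted p of 0.0672 (posterior Hox), 0.0733 (kidney function locus). With a pseudocount of 0.1 calls were lost at adjusted p of 0.0509 (kidney function locus). Without mitochondrially encoded genes calls were lost at adjusted p of 0.065 (kidney function locus). Among protein-coding genes calls were lost at adjusted p of 0.0535 (kidney function locus). Lists newly called were nephron progenitor with array weights (0.0471), podocyte with array weights (0.0332), fatty acid oxidation with the replicate block (0.00601). Lists whose test, against all other genes, turned direction, none of them called, were early nephron with a pseudocount of 0.1 (0.996), early nephron without a filter (0.606), lymphocyte without a filter (0.86), early nephron at a mean of at least 5 TPM (0.363), early nephron with the replicate block (0.584), heat shock with the replicate block (0.455), early nephron among protein-coding genes (0.811), lymphocyte among protein-coding genes (0.859), heat shock with quantile normalization (0.724), heat shock without the 25 most abundant genes (0.993). Without 1 library, the lowest and highest adjusted p of each list that changed its call or direction were 0.423 and 0.97 (DNA methylation machinery), 0.0157 and 0.457 (nephron progenitor), 0.423 and 0.992 (early nephron), 0.0156 and 0.848 (proximal tubule), 0.00602 and 0.494 (distal tubule), 9.24e-05 and 0.193 (principal cell), 0.0276 and 0.637 (intercalated cell), 9.24e-05 and 0.645 (podocyte), 0.0157 and 0.723 (endothelial), 3.01e-12 and 0.965 (fibroblast), 0.00598 and 0.315 (tubule injury), 7.12e-05 and 0.344 (macrophage), 0.0118 and 0.992 (lymphocyte), 0.00448 and 0.457 (interferon), 0.000777 and 0.123 (imprinted), 0.00266 and 0.309 (posterior Hox), 0.0148 and 0.568 (kidney function locus), 1.14e-06 and 0.384 (cell cycle), 0.0101 and 0.829 (fatty acid oxidation), 0.0168 and 0.992 (cholesterol synthesis), 0.448 and 0.965 (heat shock), 0.00463 and 0.155 (immediate early), 0.0118 and 0.384 (circadian clock), 2.6e-06 and 0.144 (mitochondrial), 4.52e-06 and 0.423 (erythroid), 0.0101 and 0.213 (adipose), 0.000849 and 0.193 (urothelial). The adipose list had too few members for a value without control replicate 1.

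The replicate numbers share 2 values between the groups and are not stated to pair animals. The difference between controls 1 and 2 correlated at 0.067 across genes with that between KspCre DKO libraries 1 and 2, and with the replicate block 47 genes were higher and 28 lower. Control replicate 3 shares its number with no other library, so in the block fit it does not enter the group difference. The fold changes of that fit are those found without control replicate 3. Depth is unknown, which leaves open which values of 0 are failed estimates.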

Other observations

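The splits of the libraries, the tests of gene copies, of thick ascending limb markers with Aqp2 and of clock phases, and the division of heat shock genes were chosen after the results were seen. Heat shock and unfolded protein genes were not called as a list, and members went both ways. In a division of 18 of the 24 tested members made after their values were seen, which leaves out 6, the 10 genes for cytosolic heat shock proteins had a mean log2 fold change of 0.53 and 5 of them were higher, while the 8 for endoplasmic reticulum chaperones and their regulators had a mean of −0.64 and 6 were lower. Hspa1b, an inducible cytosolic Hsp70, stood at 26.1 ± 9.89 TPM (SD, n = 3) against 102 ± 43.5 TPM (SD, n = 2), and Hspa5, the chaperone BiP, at 325 ± 76.5 against 138 ± 36.4 TPM. Outside the lists, Akr1b3, aldose reductase, stood at 114 ± 62.1 against 966 ± 361 TPM (limma adjusted p = 0.0541) and Cryab at 502 ± 84.0 against 1473 ± 405 TPM (adjusted p = 0.0836). Neither passed. The adrenal genes Cyp21a1 and Cyp11b1, both too low to be tested, stood at 3.63 and 1.76 TPM in control replicate 1. In the other libraries they were at most at 0.22 TPM. The highest value of any adrenal list member in a library was 15.6 TPM, and the more abundant members are not given by library here.

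Of the 10 splits of the 5 libraries into 3 and 2, the real one called 23 genes and was the 1 split with that many; the highest other split called 18, and 10 splits are too few for a share below 0.05. That other split sets controls 2 and 3 against control 1 and both KspCre DKO libraries. Its called genes included Akr1c21, at 223 TPM in control replicate 1, 2.71 and 2.42 TPM in controls 2 and 3, and 219 and 108 TPM in the KspCre DKO libraries, and Serpina1f, at 178 TPM, 16.7 and 21.1 TPM, and 169 and 145 TPM. Hsd3b2 and Hbb-bt were also among them. Of these 18 genes, 15 had a position, on 7 chromosomes.

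Copies of one gene differed unequally between the groups (Rps3a1 lower with Rps3a2 and Rps3a3 higher, Tpm3-rs7 far more than Tpm3, Hsd3b4 lower with Hsd3b2 higher). Hsd3b2 did not pass (limma adjusted p = 0.253). It stood at 59.6, 3.89 and 3.75 TPM in the controls against 170 and 108 TPM, so control replicate 1 also differed from the other controls. Reads shared between copies and assigned differently may account for the Rps3a genes, since the log2 fold change of their summed TPM was 0.0718, under its pooled SD of 0.32. The sum over 3 genes named Tpm3 moved by 1.33 (pooled SD 0.31), which argues against reads shared among these 3 alone as the whole cause. Copies of Tpm3 under other names or without a symbol are outside that sum, so reads shared with them stay open. For 9 Hsd3b genes and predicted models among them, shared reads are argued against as the whole cause only narrowly. Their sum moved by −0.25 (pooled SD 0.12) beside −6.74 for Hsd3b4, so shared reads may account for most of that. A strain-derived segment of chromosome 3 that differs between the groups cannot be told apart from a change at the Hsd3b genes alone. Of 249 bins with at least 10 tested genes, the bin from 90 to 100 Mb was the 1 called. It held 14 of 128 genes with unadjusted p below 0.01 (Fisher's exact test, adjusted p = 0.0185). Without the Hsd3b cluster it held 8 of 119 such genes and was not called (Fisher's exact test, unadjusted p = 0.0584), which leaves the segment open. Rps3a1 at 86137940 and Rplp0 on chromosome 5 lie outside that bin, Tpm3 inside it had an unadjusted p of 0.0665, and the genotype stays open as untested.

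Thick ascending limb markers were lower and Aqp2 higher. The low complexity of KspCre DKO replicate 2 is argued against as the whole cause of the first by KspCre DKO replicate 1 alone. Without KspCre DKO replicate 2 the list's median was −0.82, against 0.13 for all genes. That refit holds 1 KspCre DKO library, so it has no measure of the spread in that group. Whether more principal cells account for the Aqp2 difference of 2.0 cannot be told from the other 22 principal cell markers. Their median was 0.19 with an SD of 0.95. Aqp2 had the smallest p of that list, and the comparison was chosen after the results were seen. It could therefore exceed the median of the others with or without more principal cells. Elf5, another member, differed by 2.51, while 9 of the 23 members were lower. A lower share of cortex and outer medulla together in the tissue taken cannot be told apart from a change in the cells: the limb score less the mean of proximal tubule and podocyte scores differed by −0.82, under 2 pooled SDs of 0.46 each. The genotype stays open as a biological explanation.

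Clock genes of opposite phase had mean differences of opposite sign. With 3 of the 17 tested clock genes left out, assigned to neither phase, the 10 genes that peak with Dbp had a mean log2 fold change of 0.72 and the 4 that peak with Arntl one of −0.84, a difference of 1.56 with a pooled SD over libraries of 0.68. A different hour of tissue collection cannot be told apart from the genotype: exact permutation over the 5 libraries gave a two-sided p = 0.2, where 10 splits cannot give one below 0.1, and no collection time is given in the labels. The same difference of phases per library was 3.27, 1.72 and 2.02 in the controls and 4.06 and 3.73 in the KspCre DKO libraries, so control replicate 1 lay nearest to the latter.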
